A study of Arabidopsis thaliana with 129 samples.

How the data were processed

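The tables of the series cover 129 poly(A) RNA-seq libraries of whole Arabidopsis seedlings: 63 Col-0, 65 pifq and 1 elf3 library. Per the labels' protocols, seeds were stratified for 3 d at 4 C, given 24 h of light to germinate, and grown at 22 C and 60% humidity in clusters of 50 seeds. RNA was taken with an Omega plant kit and libraries were made with a directional NEBNext Ultra II kit. Libraries per regime in Col-0 and pifq were 16 and 20 for C1, 16 and 13 for C2, 15 and 16 for T1, and 16 and 16 for T2. The highest light level of the dawns was 27.8 µmol of photons per square metre and second.

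Reads were trimmed with Trim Galore 0.6.10, quantified with Salmon 1.10.0 and gathered per gene in R 4.5, per the submitters' processing notes. The genome build and the annotation are not given in the sources used here. The authors deposited 3 tables of all libraries: estimated counts per gene, abundances in TPM, and effective gene lengths. The deposited estimated counts are not all whole (56.3% of values within 1e-06 of a whole number) and were rounded before the tests. The deposited TPM were used only in 1 alternative, and the deposited effective lengths only as offsets and to look for length bias. Of 40215 entries 37282 matched a locus tag of a TAIR10.1 reference table, used for gene names alone. There were 1148 entries that join several locus tags, whose genes cannot be told apart, and 1539 with a number and no locus tag. No column of values was left unmatched to a sample (0). Genes with near-identical copies, such as those of LHCB1, share reads and are given as uncertain.

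Library totals ran from 19.23 to 64.34 M estimated counts (median 27.91 M). With the usual 2 libraries per group, the SE of a log2 change over the ramp was 0.08 for RVE4 at 127 CPM and 0.42 for PIL1 at 17 CPM (T1 against C1). Effects of a few SE could also fail to pass after adjustment. Low-count genes were filtered with filterByExpr over the groups, which left 27597 genes. Libraries were scaled with TMM. The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with trended dispersion, 1 mean for each of 64 groups of genotype, regime and time (4 groups of 1 library, 56 of 2 and 4 of 3), and 64 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg over all genes with threshold 0.05. The elf3 library was left out of the fit, since it is alone in its group, and is given as values. Log2 CPM used a prior count of 1.

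For genes with 0 reads in every library of a group, edgeR's test of a mean over groups tends to p near 1, because the empty group can take up any difference. This was found after the data were seen. In T1 against C1 it concerned 5464 genes, of which 30 had a mean of 5 CPM or more, 202 still passed and 11 were members of the lists. Counts of genes past 0.05 are therefore low for genes silent in part of the time course, among them DFR, LDOX, PRE5 and PIL1. In T2 against T1 15 of the 47 genes had such a group.

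Comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The comparisons were the light response in Col-0 within C1, T1 and T2; T1, T2 and C2 against C1 and T2 against T1 over the ramp in Col-0; pifq against Col-0 over all regimes and times; and the dependence on genotype of the C1 light response, of T1 against C1 and of T2 against T1. The same contrasts in the dark, on the plateau, at single times and within pifq were computed beside them.

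The 15 gene lists held 207 entries, of which 202 were tested: clock, morning-phased; clock, evening-phased; HY5 and B-box early light genes; flavonoid and anthocyanin; PIF targets and auxin-linked growth; PIF family; photoreceptors and phyA transport; chlorophyll synthesis; light-harvesting antenna; dark and sugar starvation; heat shock and excess light; touch, wound and jasmonate (handling); photoperiodic flowering; root markers; and seed storage and seed maturation. Lists were tested with camera (limma 3.58.1) on log2 CPM with the preset correlation between genes of 0.01, and again with a correlation estimated from the residuals. Of 165 list tests 53 passed 0.05 with the preset value (33 higher, 20 lower) and 34 with the estimated one. Lists with few calls are given here once. In C1 light 2 of 6 PIF family genes rose and 1 fell, and 2 of 8 photoperiodic flowering genes rose and 1 fell (median 0.07, mean -0.33); in T1 light 3 and 1 and in T2 against C1 2 and 0. In each of the 3 light responses 1 of 10 root markers, SCR, rose (0.92 ± 0.15, 0.90 and 0.90), and in C2 against C1 it was lower (-0.50).

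Genes named in the report are the 4 PIF genes mutated in pifq; ELF3, PRR9, LUX, GI, TOC1, CCA1, LHY and PIF4 in the elf3 library; per comparison the 5 largest rises and 5 largest falls past 0.05 with a mean of at least 5 CPM and a symbol; and per comparison and list up to 4 members past 0.05 with the largest change and the most highly expressed member not past it. Time courses of PIL1, ATHB2, HFR1, PRR9 and BT2 and the values of genes in comparisons outside this rule were chosen after their values were seen.

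Alternatives were RLE size factors, no filter on low counts, effective length offsets, limma-trend on log2 of TPM with a pseudocount of 1, limma-voom with the replicate series as a random block, DESeq2 1.42.0, a replicate block, counts summed per series and window, only the groups compared, only ZT0.5 and ZT1, a joint test of the 4 times, leaving out libraries whose labels disagree, leaving out each replicate series in turn, and the estimated correlation for lists. A shift of C2 by 1 h and the removal of 16 libraries that stood apart in the slope of expression on effective length (over 3 MADs) or in TMM factor (under 0.8) were added after the data were seen. To ask whether chance could give as many genes, libraries were regrouped 100 times for each comparison with limma-trend.

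Labels of 4 libraries disagree with each other: the time of P34 in its title and library number, and the treatment of P83, P85 and P87 in title and treatment field. All were kept as titled.

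The scripts were tested on simulated counts for T1 against C1 over the ramp (27597 genes, 200 of them changed). edgeR recovered 61.2% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 84.8% of those changed 4-fold, with 5.6% false calls. limma-trend and DESeq2 gave 23.2% and 23.5% false calls on the same counts. These counts were drawn once, independently for each library, with the spread that edgeR had fitted. They favour edgeR and hold no deviations shared within a series. The shares of false calls need not hold in the real data, and the simulation does not rank the tools. Camera picked out a changed list of the simulation and not an unchanged one.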

Results

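The series holds poly(A) RNA-seq libraries of Arabidopsis seedlings 7 d old, grown on plates with 1% sucrose and sampled around the start of the day. Seedlings were kept in 1 of 4 light regimes. C1 and C2 were square-wave days of 8 h and 7 h, in which light came on in 1 step. T1 was a simulated dawn in which blue, red and far-red light increased together in steps of 10 min over 2 h and then stayed level for 6 h. T2 was a dawn of the same kind in which red light started 0.5 h later and increased more steeply. Collection ran at 8 time points from ZT-0.5 to ZT3, every 0.5 h, in Col-0 and in the quadruple mutant pifq, which carries mutations in PIF1, PIF3, PIF4 and PIF5. There were 63 libraries of Col-0, 65 of pifq and 1 labelled elf3. ZT-0.5 and ZT0 are called dark here, ZT0.5 to ZT2 the ramp, and ZT2.5 and ZT3 the plateau.

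Each question was asked as 1 contrast of group means in a single edgeR fit to 128 libraries and 27597 genes. A light response is the mean of the 4 ramp times minus the mean of the 2 dark times within a regime. No group was labelled as a dark control at the ramp times, so a light response also holds any change with time of day. A regime comparison is the difference of 2 regimes over the ramp. Values below are mean CPM ± SD across libraries, log2 changes ± SE, and edgeR p-values adjusted over all genes. For single genes the SE is the size of the log2 change divided by the square root of the F statistic. It thus follows from the test and was not estimated apart from it. A count such as 7 of 8 gives how many libraries of the group named first lay on the stated side of the mean of the other group. Most groups had 2 libraries, and nothing in the labels says that these came from separately grown plates, so p-values measure the spread between these samples.

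Replicate libraries correlated at 0.8445 to 0.99 (median 0.9698 over 68 pairs). Chloroplast-encoded reads made up 0.291% of the total in the median library and 2.77%, 2.5% and 2.23% in P64, C55 and P16. The 10 genes of seed storage and seed maturation were uneven between libraries: their mean log2 CPM was 4.77 ± 1.59 in C1 Col-0 (n = 16), 3.85 ± 0.95 in T1 Col-0 and 4.96 ± 0.74 in T2 Col-0. The highest single value, 7.5, was that of C06, a C1 Col-0 library of ZT2.

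All 4 PIF genes had fewer reads in pifq. Across all times and regimes PIF5 (-3.31 ± 0.05, adjusted p = 2.62e-62, 15.7 ± 3.34 against 154 ± 21.8 CPM) and PIF3 (-3.56 ± 0.09, adjusted p = 3.89e-47, 2.8 ± 1.39 against 31.7 ± 6.94 CPM) were the most reduced. PIF1 (-1.30 ± 0.04, adjusted p = 1.16e-38, 22.1 ± 5.96 against 53.9 ± 10.8 CPM) and PIF4 (-0.90 ± 0.04, adjusted p = 1.28e-28, 58.7 ± 13.9 against 110 ± 30.4 CPM) kept more transcript. The pifq libraries below every Col-0 library numbered 61 for PIF1, 65 for PIF3, 31 for PIF4 and 65 for PIF5.

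**Figure D1:**
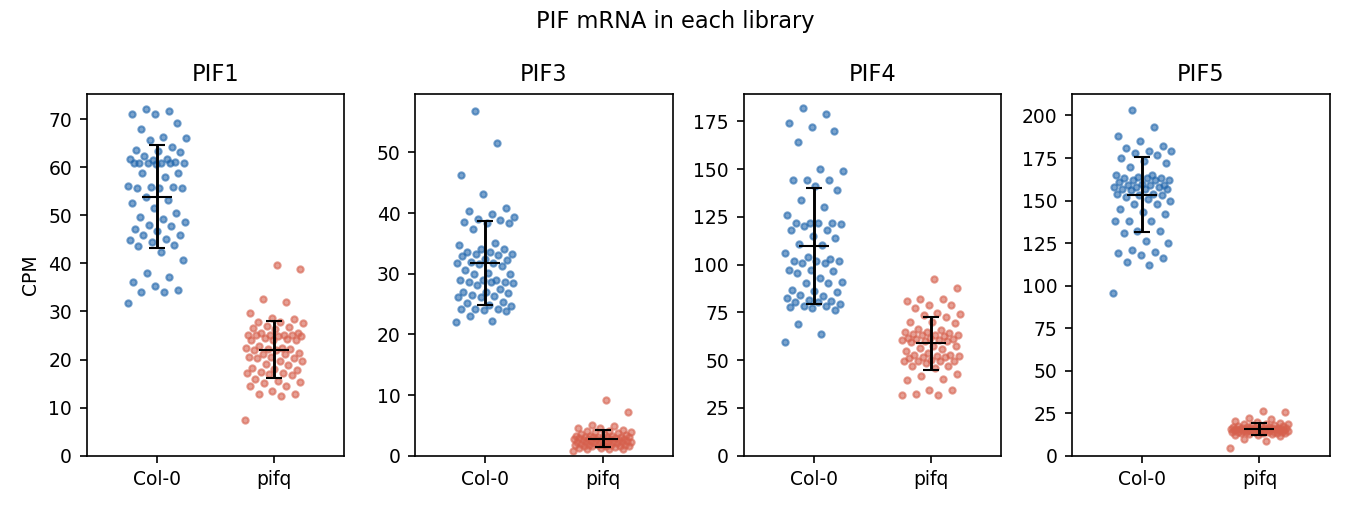
CPM of PIF1, PIF3, PIF4 and PIF5 in each Col-0 and pifq library, all regimes and times together. Points are libraries and bars show the mean ± SD.

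The first question was how Col-0 differs between the dark and the 2 h after a sudden start of light. In C1 the early photoprotection gene ELIP1 rose from 0.647 ± 0.444 to 25.6 ± 16.1 CPM (5.01 ± 0.48, adjusted p = 4.14e-14, 8 of 8). The clock gene PRR9 rose from 5.58 ± 1.12 to 135 ± 46.1 (4.52 ± 0.18, adjusted p = 8e-33) and the bHLH gene PIL1 from 0.558 ± 0.372 to 17 ± 7.8 (4.95 ± 0.69, adjusted p = 1.83e-08). BT2, which encodes a BTB-TAZ scaffold protein repressed by sugar, fell from 348 ± 99.3 to 18.8 ± 9.06 CPM (-4.31 ± 0.14, adjusted p = 4.04e-38). The asparagine synthetase gene DIN6 fell from 273 to 54.4 CPM (-2.96 ± 0.27, adjusted p = 4.13e-15). In total 5840 genes passed 0.05, 2942 higher and 2898 lower in the light, of which 780 and 590 by at least 2-fold (8 ramp and 4 dark libraries).

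By list, 15 of 23 HY5 and B-box early light genes rose in C1 and 2 fell (16 and 3 adjusted over the list alone, camera adjusted p = 1.02e-05 with an estimated correlation). The largest rises were those of BBX30 (3.37 ± 0.33), BBX31 (3.23 ± 0.26) and BBX29 (3.07 ± 0.20). In the flavonoid and anthocyanin list 13 of 19 rose and 6 did not pass (14 higher and 1 lower adjusted over the list alone, adjusted p = 1.18e-06 with an estimated correlation). Among them were the chalcone synthase gene CHS (27.3 against 1.78 CPM, 3.39 ± 0.36) and F3H, which acts downstream of it (141 against 14.1 CPM, 3.08 ± 0.15). Of 20 PIF targets and auxin-linked growth genes 13 rose and 2 fell (14 and 3 adjusted over the list alone, adjusted p = 1.02e-05 with an estimated correlation). The homeobox gene ATHB2 (59.1 against 8.63 CPM, 2.47 ± 0.16) and HFR1 (155 against 27.7 CPM, 2.46 ± 0.15) rose and PKS4 fell (-2.22 ± 0.80). All 14 dark and sugar starvation genes fell (adjusted p = 0.000576 with an estimated correlation). Of 13 heat shock and excess light genes 7 rose (8 adjusted over the list alone, adjusted p = 0.000248 with an estimated correlation). These included HSFA2 (19.2 against 1.22 CPM, 3.47 ± 0.41), ROF2 (3.04 ± 0.26) and HSP101 (1.80 ± 0.16).

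Clock genes moved both ways in C1. Of 15 morning-phased genes 4 rose and 7 fell. RVE2 (-2.57 ± 0.14), RVE4 (127 against 564 CPM, -2.24 ± 0.09) and RVE1 (-1.61 ± 0.10) fell, and CCA1 stood at -0.01 ± 0.10 (adjusted p = 1, 4 of 8). Of 10 evening-phased genes 2 rose and 3 fell, GI being highest (73.3 against 9.27 CPM, 2.79 ± 0.25). The median of that list was -0.27 and its mean 0.36, and neither clock list passed camera (adjusted p = 0.172 and 0.96). Among photoreceptors PHYB rose from 82.8 to 272 CPM (1.70 ± 0.19), CRY1 fell (-0.56) and the counts were 4 up and 4 down of 13. Of 15 chlorophyll synthesis genes 6 rose and 3 fell. GLK1 (1.51 ± 0.15), SIG5 (1.26 ± 0.07) and GUN4 (0.79 ± 0.10) rose, CHLM fell (-0.75 ± 0.08) and CHLH stood at 0.07 (adjusted p = 0.897, 2430 against 2300 CPM). Of 15 antenna genes 4 rose and 2 fell. Of 11 touch, wound and jasmonate genes 3 rose, including LOX3 (1.49 ± 0.23). CDF2, which encodes a repressor of CO, fell (-1.99 ± 0.10). Over ZT0.5 and ZT1 alone 3711 genes passed and CCA1 stood at 0.46, with only these groups in the fit 8920 passed, and without 1 replicate series 3124 or 3666.

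The same question was asked of the 2 dawns. In T1 5196 genes passed 0.05 (2624 higher, 2572 lower) and in T2 5769 (3071 higher, 2698 lower, but 1917 and 4659 with limma-trend on TPM). PRR9 rose from 2.54 to 174 CPM in T1 (6.03 ± 0.20, adjusted p = 5.46e-38) and from 3.16 to 160 CPM in T2 (5.35 ± 0.19, adjusted p = 8.91e-36). ELIP1 (5.30 ± 0.47 and 4.64 ± 0.46) and GI (4.09 ± 0.28 and 3.64 ± 0.27) were also among the largest rises. BT2 fell in both (-3.21 ± 0.13 and -3.26 ± 0.13), as did DIN6 (-2.35 ± 0.26 and -2.90 ± 0.26) and DIN1 (-2.25 ± 0.28 and -2.84 ± 0.28). GATA4 fell in T1 from 150 to 29.5 CPM (-2.40 ± 0.12).

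Of 23 HY5 and B-box genes 18 rose and 1 fell in T1, and 19 rose and 2 fell in T2 (adjusted p = 3.39e-09 and 1.84e-08 with an estimated correlation). BBX31 stood at 4.18 ± 0.28 in T1 and BBX32 at 4.43 ± 0.27 in T2 (40.4 against 1.45 CPM). Flavonoid genes rose in 10 and 11 cases with 0 lower (adjusted p = 8.41e-07 and 8.29e-06 with an estimated correlation), F3H by 3.11 ± 0.15 and 3.07 ± 0.15. Dark and sugar starvation genes fell in 13 and 14 of 14 cases (adjusted p = 0.0133 and 0.00345 with an estimated correlation). Heat shock and excess light genes rose in 7 and 6 of 13 (adjusted p = 0.00462 and 0.00345 with an estimated correlation), for example HSFA2 (2.42 in T1, 2.77 in T2). Of 15 antenna genes 8 rose in T1 and 11 in T2, LHCB3 by 0.79 and by 1.11 ± 0.13 (in T2 3120 against 1470 CPM). For that list adjusted p = 0.587 and 0.172 with an estimated correlation. Chlorophyll synthesis genes rose in 6 cases and fell in 3 in T1, and rose in 9 and fell in 4 in T2, with adjusted p = 0.258 and 0.129 with an estimated correlation.

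PIF targets did not pass as a list in either dawn. In T1 3 of 20 rose and 7 fell (5 and 7 adjusted over the list alone, median -0.29, camera adjusted p = 0.37). In T2 3 rose and 6 fell (4 and 8 adjusted over the list alone, median -0.26, camera adjusted p = 0.0718). PAR1 fell in both (-1.92 ± 0.29 and -2.43 ± 0.29), the auxin-response gene IAA29 fell (-1.59 ± 0.40 and -2.19 ± 0.41), and XTR7 fell in T2 from 53.3 to 18.6 CPM (-1.66 ± 0.23). ATHB2 was 34.5 against 28.2 CPM in T1 (0.19 ± 0.14, adjusted p = 0.447) and 48.9 against 30.5 CPM in T2 (-0.24 ± 0.14, adjusted p = 0.262). The T2 value of ATHB2 turned to 0.58 over ZT0.5 and ZT1 alone and to 1.04 with counts summed per series and window. Over ZT0.5 and ZT1 alone 2500 genes passed in T1 and 2955 in T2, and with only these groups in the fit 2678 passed in T2. Without 1 replicate series 3023 or 3109 passed in T1 and 3601 or 5324 in T2.

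**Figure D2:**
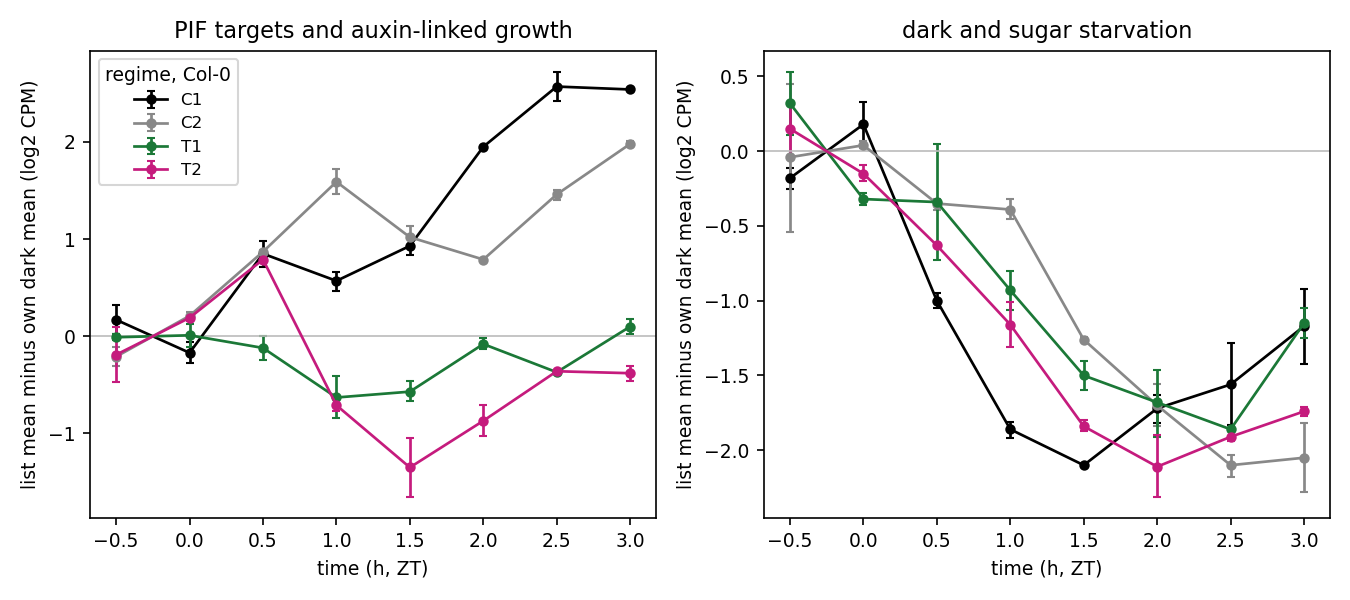
Mean log2 CPM of the PIF target and the dark and sugar starvation lists in Col-0, minus the mean of the same regime in the dark, against time (ZT, h) for the 4 regimes. Bars run from the lowest to the highest library.

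The time courses separate the start of the dawns from their later part. In Col-0 ATHB2 stood at 103 ± 7.13 CPM at ZT0.5 in C1, 52.1 ± 9.34 in T1 and 150 ± 11.6 in T2 (n = 2 each), and at ZT1 at 14.6 ± 1.02, 20.4 and 13.7 ± 4.01. By ZT2.5 it was 86.6, 38.2 and 36.7 CPM, with a single T1 library. The C1 library C17 of that time stood apart. PIL1 was 19.4 ± 2.57, 5.31 ± 3.29 and 25.7 ± 5.61 CPM at ZT0.5 in C1, T1 and T2, and 25.8, 9.43 and 2.6 CPM at ZT2. PRR9 was 157 ± 4.87, 107 ± 11.8 and 36.8 ± 0.865 CPM at ZT0.5 and 192 ± 0.882, 262 ± 0.375 and 232 ± 60.6 CPM at ZT1. Genes past 0.05 against the dark of the same regime numbered 1574 at ZT0.5 in C1, 962 in T1 and 377 in T2, and 4021, 2696 and 4444 at ZT1. With the series as a random block in limma-voom the counts were 2014, 2067 and 1500 at ZT0.5 and 4457, 3382 and 4333 at ZT1. The lower count of T1 than of C1 at ZT0.5 did not hold there. The T2 libraries C63 (ZT0.5, length slope -0.257) and C64 (ZT1, TMM factor 0.765) and the T1 library C54 (ZT1, -0.213) stood apart. Without such libraries the counts were 2357, 1140 and 911 at ZT0.5 and 5318, 3258 and 2758 at ZT1, so the higher count of T2 than of T1 at ZT1 did not hold.

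**Figure D3:**
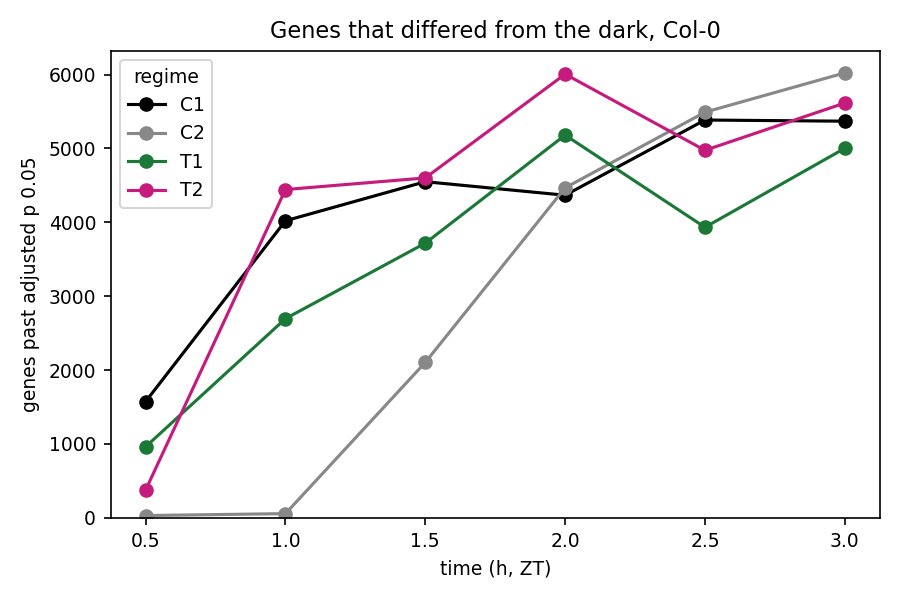
Number of genes past 0.05 against the dark libraries of the same regime in Col-0, by time (ZT, h), for the 4 regimes.

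The next question was how seedlings under a gradual dawn differ from those under a sudden one over the same 2 h. A highest light level is given for the dawns and not for C1, and the regimes also differed in the dark. The shape of the dawn can therefore not be told apart from light level or other differences between the regimes. Compared with C1, T1 Col-0 had more DIN1 (43.9 ± 51.3 against 8.79 ± 6.84 CPM, 2.11 ± 0.26, adjusted p = 4.24e-09, 7 of 8) and more of the branched-chain aminotransferase gene BCAT2 (24.2 against 6.24 CPM, 1.97 ± 0.26, adjusted p = 2.48e-08, 7 of 8). It also had more AGT3 (79.3 against 20.4 CPM, 1.87 ± 0.23, adjusted p = 3.34e-09) and more of the cold- and clock-regulated gene COR27 (10.3 against 2.02 CPM, 2.19 ± 0.23, adjusted p = 1.43e-11). The jasmonate synthesis gene LOX2 was lower (9.05 ± 4.76 against 107 ± 70.1 CPM, -3.25 ± 0.32, adjusted p = 3.25e-12). In total 3202 genes passed 0.05, 1664 higher and 1538 lower in T1, with 97 and 392 by at least 2-fold (8 against 8 libraries). The split was 1178 and 1946 with limma-trend on TPM, and 553 and 149 with counts summed per series and window.

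Of 14 dark and sugar starvation genes 13 were higher in T1 (14 adjusted over the list alone, median 0.87, adjusted p = 0.000415 with an estimated correlation). These included DRM1 (106 against 43.1 CPM, 1.25 ± 0.15, adjusted p = 1.66e-09) and DIN6 (139 against 54.4 CPM, 1.42 ± 0.23, 4 of 8). Of 15 morning-phased clock genes 10 were higher and 0 lower (11 and 0 adjusted over the list alone, median 0.36, adjusted p = 0.000415 with an estimated correlation). RVE4 (259 against 127 CPM, 0.99 ± 0.08, adjusted p = 1.98e-15) and RVE1 (0.83 ± 0.08) led, and CCA1 stood at 0.19 ± 0.08 (adjusted p = 0.149). Among evening-phased genes 2 of 10 were lower, ELF4 (-2.03 ± 0.52) and PRR3 (-0.72). PIF targets were lower in 10 of 20 cases and higher in 1 (11 and 1 adjusted over the list alone, median -0.47, adjusted p = 0.000415 with an estimated correlation). Lower were IAA29 (1.86 against 7.34 CPM, -1.62 ± 0.35, adjusted p = 0.000549), the auxin synthesis gene YUC2 (4.65 against 9.68 CPM, -1.14 ± 0.19, adjusted p = 1.26e-05) and PIL1 (5.95 against 17 CPM, -1.41 ± 0.42, adjusted p = 0.0171), with HFR1 at -0.15 ± 0.10 (adjusted p = 0.425).

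Of 23 HY5 and B-box genes 8 were higher in T1 and 0 lower (median 0.22, adjusted p = 0.00109 with an estimated correlation). These included the photolyase gene UVR3 (14.2 against 4.35 CPM, 1.66 ± 0.16, adjusted p = 3.78e-12, 6 of 8) and HYH (74 against 51.8 CPM, 0.60 ± 0.15). Flavonoid genes were lower in 7 of 19 cases and higher in 1 (median -0.52, camera adjusted p = 0.00551, adjusted p = 0.0524 with an estimated correlation), and CHS was lower as well (-0.96 ± 0.25, adjusted p = 0.00427, 5 of 8). The CO repressor gene CDF2 was higher (42.7 against 21.1 CPM, 0.84 ± 0.09, adjusted p = 7.95e-12, 6 of 8) as were 4 of 8 photoperiodic flowering genes (adjusted p = 0.0524 with an estimated correlation). CRY2, a blue light receptor gene, was higher (125 against 91.9 CPM, 0.44 ± 0.09, adjusted p = 0.000242). In the heat shock list 1 gene was higher and 4 lower (ZAT12 0.59 ± 0.15, ROF2 -0.64 ± 0.17). In the handling list TCH4 was higher (1.09 ± 0.20, adjusted p = 5.73e-05) and LOX3 lower (6.82 against 12.9 CPM, -0.95 ± 0.18, adjusted p = 5.97e-05). Of 10 seed storage genes 5 were lower in T1, among them SESA2 (2.67 against 39.7 CPM, -3.87 ± 0.96, adjusted p = 0.00326). The list had adjusted p = 0.148 with an estimated correlation, and library C06 held its highest C1 value. Leaving out 1 replicate series at a time gave 1298 to 3535 genes, a joint test of the 4 times 1936, and counts summed per series and window 702. Summing ended the calls of HYH, CHS, IAA29, PIL1, YUC2, ROF2, ZAT12, LOX3, ELF4, PRR3 and SESA2.

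The second dawn differed from C1 in 3392 genes, 1866 higher and 1526 lower in T2, with 80 and 297 by at least 2-fold (8 against 8 libraries). The split was 1075 and 2793 with limma-trend on TPM, 1340 and 2110 without T2 Col-0 replicate 1, 1842 and 2281 without the libraries that stood apart, and 544 and 178 with counts summed per series and window. Higher were COR27 (1.89 ± 0.23), DIN1 (34.5 against 8.79 CPM, 1.65 ± 0.26, adjusted p = 1.9e-06, 6 of 8), UVR3 (11.8 against 4.35 CPM, 1.61 ± 0.16, 7 of 8) and the actin depolymerizing factor gene ADF9 (14.3 against 4.5 CPM, 1.53 ± 0.17, adjusted p = 1.97e-10). Lower were LOX2 (15.6 against 107 CPM, -2.45 ± 0.31, adjusted p = 9.56e-09), the expansin gene EXPB3 (44.7 ± 38.5 against 179 ± 100 CPM, -2.14 ± 0.15, adjusted p = 8.4e-18) and ECS1 (40.6 against 159 CPM, -1.92 ± 0.17).

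In T2 13 of 14 dark and sugar starvation genes were higher than in C1 (median 0.87, adjusted p = 0.00221 with an estimated correlation), BCAT2 by 1.49 ± 0.26 and DIN10 by 1.03 ± 0.21. Morning-phased clock genes were higher in 10 of 15 cases (10 higher and 3 lower adjusted over the list alone, median 0.33, adjusted p = 0.0103 with an estimated correlation). Among them were RVE4 (267 against 127 CPM, 1.00 ± 0.08, 7 of 8), RVE1 (0.74) and LHY (608 against 466 CPM, 0.48 ± 0.08). The LHY value is that of the entry of this locus alone, and reads of any entry that joins it with another locus are not in it. Of 10 evening-phased genes 3 were lower, ELF4 (-2.63 ± 0.53), FKF1 (-2.08) and GI (70.5 against 73.3 CPM, -0.59 ± 0.18, adjusted p = 0.0166, 3 of 8). PIF targets were lower in 10 of 20 (12 lower and 1 higher adjusted over the list alone, median -0.58, adjusted p = 0.000181 with an estimated correlation). Lower were PIL1 (8.14 against 17 CPM, -1.88 ± 0.43, adjusted p = 0.00119, 6 of 8), IAA29 (-1.93 ± 0.36) and ATHB2 (48.9 ± 62.8 against 59.1 CPM, -0.90 ± 0.12, adjusted p = 1.55e-08, 6 of 8).

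HY5 and B-box genes were higher in 6 of 23 cases (8 adjusted over the list alone, median 0.27, adjusted p = 0.013 with an estimated correlation), HY5 itself by 0.43 ± 0.11. Flavonoid genes were lower in 5 of 19 and higher in 1 (median -0.49, adjusted p = 0.083 with an estimated correlation). The lower ones included the anthocyanin regulator gene PAP1 (-2.23 ± 0.56), 4CL3 (-1.37 ± 0.27) and CHIL (-0.85 ± 0.19). The receptor genes CRY2 (0.49 ± 0.09) and PHYA (267 against 187 CPM, 0.48 ± 0.12) were higher, PORB (-0.53 ± 0.11) and GLK1 (-0.47) lower, and the plastid sigma factor gene SIG5 higher (0.42 ± 0.06). CDF2 was higher (0.77 ± 0.09), and the seed storage gene CRA1 was level (0.01, adjusted p = 1). Over ZT0.5 and ZT1 alone ATHB2, IAA29, PORB, HY5 and SIG5 stood at 0.22, 0.47, 0.13, -0.12 and -0.29. Leaving out 1 replicate series gave 1482 to 3450 genes, only the groups compared 2253, and counts summed per series and window 722. Summing put ATHB2 at 0.03 and ended the calls of GI, FKF1, IAA29, PIL1, HY5, PAP1, 4CL3, CHIL, GLK1 and DIN10.

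The comparison of T2 with T1 asked what a later and steeper red component changes. Over the ramp 47 genes passed 0.05, 40 higher and 7 lower in T2 (24 and 3 by at least 2-fold). The PIF-family gene PIF6 was higher (15.1 ± 5.09 against 7.01 ± 1.77 CPM, 1.07 ± 0.16, adjusted p = 8.6e-05, 8 of 8). Also higher were TSPO (287 ± 191 against 126 ± 25.5 CPM, 1.08 ± 0.19, adjusted p = 0.000849, 8 of 8), the nitrile-specifier gene NSP2 (63.5 ± 31 against 18.1 ± 6.26 CPM, 1.72 ± 0.36, adjusted p = 0.0182, 8 of 8) and MSRB4 (11.4 against 6.33 CPM, 0.85 ± 0.17, adjusted p = 0.00691). Lower were the protochlorophyllide oxidoreductase gene PORA (0.348 ± 0.246 against 7.15 ± 6.47 CPM, -4.17 ± 0.83, adjusted p = 0.00787, 8 of 8), CP1 (-0.98 ± 0.23, adjusted p = 0.0385, 7 of 8) and PAP8 (-0.42 ± 0.10, adjusted p = 0.0385, 7 of 8). Without T1 Col-0 replicate 1 or 2 PORA stood at -2.38 or -1.56. Its call was lost with sums per series (-4.57, edgeR adjusted p = 0.923) and with only the groups compared (-4.19, edgeR adjusted p = 0.531). It was also lost with the series as a random block (-3.14, limma-voom adjusted p = 0.391). The seed storage list had median 1.31 with 6 of 10 members higher adjusted over the list alone (adjusted p = 0.121 with an estimated correlation), and CRA1 was 3950 against 1240 CPM (1.45 ± 0.43, adjusted p = 0.159). That list was uneven between libraries (mean log2 CPM 4.96 ± 0.74 in T2 and 3.85 ± 0.95 in T1 Col-0, all times). Whether different amounts of seed material moved PIF6 and the other genes named was not tested. The morning-phased clock list had median -0.04 (camera adjusted p = 0.0357; adjusted p = 0.623 with an estimated correlation). Counts summed per series and window left 0 genes with edgeR (47 before, and 255 with DESeq2 on the single libraries), only the groups compared left 4, and leaving out 1 replicate series gave 69 to 409. With limma-trend on TPM 40 genes were higher and 26 lower. The direction was not stable: without T2 Col-0 replicate 1 71 genes were higher and 338 lower, without T2 Col-0 replicate 2 109 and 179, and without the libraries that stood apart 80 and 96. The real grouping gave 27 genes with limma-trend and other groupings of the same libraries up to 58, so chance could not be excluded for this count.

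By time, more genes than over the ramp differed at ZT0.5 and ZT1 alone. At ZT0.5 224 genes passed 0.05 (188 higher and 36 lower in T2, 2 against 2 libraries), of which 72 had a mean of 5 CPM or more (50 higher, 22 lower). With the series as a random block in limma-voom 1275 passed (747 higher, 528 lower). The T2 library C63 of that time stood apart in length slope (-0.257). Without such libraries, which leaves 1 T2 library, 388 genes were higher and 459 lower, and with limma-trend on TPM 176 and 276, so no direction is drawn. Higher were the shade-responsive homeobox genes ATHB2 (150 ± 11.6 against 52.1 ± 9.34 CPM, 1.52 ± 0.23, adjusted p = 1.91e-05) and HB4 (19.5 ± 1.42 against 2.52 CPM, 2.94 ± 0.49, adjusted p = 0.000158), the sulfotransferase gene ST2B (28.5 against 4.68 CPM, 2.60 ± 0.50, adjusted p = 0.00128) and PIF6 (1.74 ± 0.33, adjusted p = 0.00124). Lower were PRR9 (36.8 ± 0.865 against 107 ± 11.8 CPM, -1.54 ± 0.23, adjusted p = 1.51e-05) and PIF7 (-1.39 ± 0.25, adjusted p = 0.000396). In the PIF target list 2 members passed (7 adjusted over the list alone, median 0.69, adjusted p = 0.000124 with an estimated correlation). In the morning-phased clock list 2 of 15 were lower (7 adjusted over the list alone, median -0.41, adjusted p = 0.0217 with an estimated correlation). At ZT1 380 genes passed, with HFR1 now lower in T2 (63.9 ± 29.1 against 132 ± 4.45 CPM, -1.04 ± 0.21, adjusted p = 0.00624), and 1 of the T2 libraries of that time, C64, stood apart (TMM factor 0.765, replicate correlation 0.9027, antenna mean log2 CPM 12.12 against 11.16). The T1 library C54 also did (length slope -0.213). Without such libraries, which leaves 1 library on each side, 105 genes passed (87 higher, 18 lower, against 180 and 200), and with limma-trend on TPM 199 were higher and 902 lower. At ZT1.5, ZT2, ZT2.5 and ZT3 there were 1, 0, 6 and 1 genes with edgeR, with a single T1 library at ZT2.5 (634, 1732, 738 and 1232 at unadjusted p = 0.05), and at ZT-0.5 and ZT0 0 each with edgeR (2327 and 245 at unadjusted p = 0.05).

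The regimes already differed before light came on. In the dark (4 against 4 libraries) 118 genes separated T1 from C1 and 276 separated T2 from C1. At ZT-0.5 alone the counts were 266 and 278 and at ZT0 alone 15 and 14 (2 against 2 libraries). With the series as a random block in limma-voom the dark counts were 65 and 308, and those of ZT-0.5 388 and 478. With limma-trend on TPM those of ZT-0.5 were 286 and 530. The T1 library C51 of ZT-0.5 stood apart (length slope -0.335, replicate correlation 0.929). Without such libraries in the whole fit the dark counts were 129 and 733, and those of ZT-0.5 212 and 746, although no dark Col-0 library of T2 or C1 was left out. HFR1 was 94.7 ± 3.99 CPM in T1 and 27.7 ± 7.16 in C1 (1.81 ± 0.15, adjusted p = 7.43e-14), and ATHB2 28.2 ± 3.2 and 8.63 ± 1.61 (1.70 ± 0.17, adjusted p = 3.32e-11). In T2 ATHB2 was 30.5 CPM (1.81 ± 0.17), HFR1 89 CPM (1.71 ± 0.15) and XTR7 53.3 against 17.2 CPM (1.63 ± 0.28). As a list, PIF targets were higher in 4 of 20 cases in T1 (8 adjusted over the list alone, median 0.66, adjusted p = 2.63e-10 with an estimated correlation) and in 6 in T2 (13 adjusted over the list alone, median 0.93, adjusted p = 6.7e-11 with an estimated correlation). DIN1 was higher in T2 (1.58) and BCAT2 as well (1.55), GI was lower (-1.43), and in T2 the antenna genes LHCB3 (-0.77) and LHCB5 (-0.67) were lower.

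On the plateau 784 genes separated T1 from C1 (3 against 4 libraries) and 1411 separated T2 from C1 (4 against 4). The C1 library C17 stood apart in length slope (-0.441), and without such libraries the counts were 675 and 1128. With the series as a random block in limma-voom they were 1751 and 1703. The desaturase gene ADS1 stood at 6.63 CPM in T1, 8.93 in T2 and 118 in C1 (-4.68 ± 0.52 and -3.60 ± 0.39). The auxin-response gene IAA19 stood at 3.83 and 24.4 CPM in T1 and C1 (-2.89 ± 0.51), and IAA29 at 3.35 and 35.8 CPM (-3.60 ± 0.64). PIF targets were lower in 15 of 20 cases in T1 (median -1.63, adjusted p = 2.54e-15 with an estimated correlation) and 17 in T2 (median -1.78, adjusted p = 4.37e-16 with an estimated correlation). HY5 was higher in both (1.17 ± 0.17 and 1.45 ± 0.16), also HSFA2 (1.76 and 2.02), F3H (1.07 and 1.57 ± 0.15) and SIG5 (1.08 ± 0.09 and 0.95). PORB was lower (-1.46 ± 0.19 and -1.61 ± 0.16), and 8 HY5 and B-box genes were higher in each dawn and 1 lower in T2 (adjusted p = 0.00368 and 0.00581 with an estimated correlation).

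C2 was compared with C1 to ask whether a shorter square-wave day alters the response. PRR9 was lower in C2 over the ramp (92.8 against 135 CPM, -2.13 ± 0.12, adjusted p = 3.31e-24, 5 of 8). ELIP1 (12.1 against 25.6 CPM, -2.99 ± 0.33, adjusted p = 3.93e-11, 6 of 8) and CHS (5.26 against 27.3 CPM, -2.49 ± 0.26) were also lower, and BT2 was higher (186 ± 175 against 18.8 ± 9.06 CPM, 2.36 ± 0.12, adjusted p = 1.08e-25, 6 of 8). In total 3980 genes passed 0.05, 1709 higher and 2271 lower in C2, with 104 and 355 by at least 2-fold. The split was 2378 higher and 1752 lower with limma-trend on TPM, and 718 and 570 with counts summed per series and window. By time, PRR9 in C2 was 4.07 ± 1.21 CPM at ZT0.5, 5.37 ± 0.556 at ZT1, 150 ± 26.9 at ZT1.5 and 212 ± 15.7 at ZT2, against 157 ± 4.87 and 192 ± 0.882 at ZT0.5 and ZT1 in C1. BT2 in C2 was 350 and 347 CPM at ZT0.5 and ZT1 and 27.7 at ZT1.5. Against its own dark C2 had 31 genes past 0.05 at ZT0.5, 57 at ZT1 and 2104 at ZT1.5.

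In C2 relative to C1 flavonoid genes were lower in 11 of 19 cases (14 adjusted over the list alone, adjusted p = 2.45e-07 with an estimated correlation), and HY5 and B-box genes lower in 13 of 23 and higher in 2 (adjusted p = 0.00126 with an estimated correlation). Heat shock and excess light genes were lower in 6 of 13 (7 adjusted over the list alone, adjusted p = 0.0038 with an estimated correlation) and PIF targets lower in 5 of 20 and higher in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.00978 with an estimated correlation). Dark and sugar starvation genes were higher in 13 of 14 cases (adjusted p = 0.00405 with an estimated correlation). Antenna genes were lower in 8 of 15 (adjusted p = 0.562 with an estimated correlation), and chlorophyll synthesis genes lower in 6 and higher in 1 of 15 (adjusted p = 0.245 with an estimated correlation). Morning-phased clock genes were higher in 8 and lower in 3 of 15 (adjusted p = 0.15 with an estimated correlation). Single genes lower in C2 included FBA5 (58.1 against 267 CPM, -3.12 ± 0.16), PIL1 (3.16 against 17 CPM, -2.63 ± 0.45), HSFA2 (-1.40), ROF2 (-1.43), GI (-1.39 ± 0.18), GLK1 (-0.98) and PIF7 (-1.11 ± 0.12). RVE4 (332 against 127 CPM, 1.21 ± 0.08), DIN6 (160 against 54.4 CPM, 1.76 ± 0.23) and CDF2 (1.00 ± 0.09) were higher. ATHB2 and HFR1 had higher values before ZT1.5. ATHB2 stood at 43.2 ± 6.7 CPM at ZT0.5 and 112 ± 9.37 at ZT1 in C2, from 7.43 at ZT0, and HFR1 at 65.1 ± 16.6 and 149 ± 8.74, from 25.3. If light came on 1 h later in C2 than in C1, both rose there without light. Part of their rise in the C1 light response may then be time of day. Over 3759 genes past 0.05 in the light responses of both T1 and T2, the C2 change had slopes of 0.13 (ZT0.5) and 0.05 (ZT1) on the C1 change. If C2 was still dark then, these values argue against time of day as the main source of the C1 change up to ZT1. They cover these genes as a set, and no later ramp time. When C2 libraries were compared with C1 libraries collected 1 h earlier, a comparison added after the data were seen, 46 genes passed, 9 higher and 37 lower, and PRR9, BT2, CHS and ELIP1 stood at 0.12, -0.13, 0.25 and 0.28. Without 1 replicate series the count fell to 2508 to 2739, and with counts summed per series and window it was 1288.

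The pifq comparison asked how the mutant differs from Col-0, with all times and regimes averaged (65 against 63 libraries). Differences of seed stock or genetic background between the genotypes cannot be told apart from the mutations in the 4 PIF genes. PIL1 was lower (1.52 against 7.97 CPM, -3.09 ± 0.19, adjusted p = 9.06e-22, 65 of 65), as was HFR1 (61.8 against 121 CPM, -1.11 ± 0.04, adjusted p = 7.8e-37, 64 of 65). ATHB2 was lower too (26.7 against 41.9 CPM, -0.52 ± 0.04, 50 of 65). The orphan gene QQS was higher (34.4 ± 11 against 0.452 ± 0.408 CPM, 6.73 ± 0.18, adjusted p = 1.01e-43, 65 of 65). DIN6 was higher (294 against 182 CPM, 0.90 ± 0.08, 35 of 65), and PGL2 was lower (1.72 against 9.88 CPM, -2.53 ± 0.08, 65 of 65). In total 6109 genes passed 0.05, 3326 higher and 2783 lower in pifq, but only 82 and 151 by at least 2-fold. The split was 2498 and 4054 with limma-trend on TPM, and 4346 and 2401 without T2 Col-0 replicate 1. Within single regimes the count was uneven: 1220 genes passed in C1, 1347 in C2, 3971 in T1 and 1006 in T2.

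In pifq 9 of 20 PIF targets were lower and 0 higher (median -0.15, adjusted p = 1.89e-05 with an estimated correlation), with IAA29 at -1.03 ± 0.13 and HAT2 at 0.07 (adjusted p = 0.169). Of 15 antenna genes 14 were higher (median 0.21, camera adjusted p = 1.55e-09, adjusted p = 0.09 with an estimated correlation), for example LHCA1 (0.26) and LHCA4 (0.25 ± 0.03). LHB1B1 stood at 1730 against 745 CPM (1.19 ± 0.06), and since the LHCB1 copies share reads its level is uncertain. Chlorophyll synthesis genes were higher in 9 of 15 and lower in 2 (adjusted p = 0.0463 with an estimated correlation), PORB at 0.41 ± 0.04 and GLK1 at -0.30. Morning-phased clock genes were higher in 11 of 15 (12 adjusted over the list alone, median 0.16, adjusted p = 0.00884 with an estimated correlation), led by PRR5 (0.32), RVE7 (0.29 ± 0.04) and RVE4 (0.25 ± 0.03). Dark and sugar starvation genes were higher in 10 of 14 (12 adjusted over the list alone, adjusted p = 0.0463 with an estimated correlation).

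Photoreceptor genes were lower in 5 of 13 cases and higher in 2, with PHYB (153 against 204 CPM, -0.44 ± 0.05), PHYD (-0.34) and PHYA (-0.22) lower and FHY1 (0.31) higher. Within the PIF family PIF7 was higher (38 against 27.9 CPM, 0.43 ± 0.04) and PIF6 lower (-0.42 ± 0.06). The list as a whole was lower in 5 of 6 cases (adjusted p = 3.08e-13 with an estimated correlation). Of its members 4 are the genes mutated in pifq, so this list test was fixed by the genotype. Photoperiodic flowering genes were higher in 3 of 8 (adjusted p = 0.0263 with an estimated correlation). Flavonoid genes were higher in 3 and lower in 4 of 19 (TT7 -0.74 ± 0.11, MYBL2 0.43 ± 0.04), and HY5 and B-box genes were higher in 4 and lower in 2 of 23 (adjusted p = 0.149 with an estimated correlation). Seed storage genes were lower in 9 of 10 (median -1.74, adjusted p = 0.000186 with an estimated correlation), the cruciferin gene CRC at 377 against 936 CPM (-1.96 ± 0.26, 59 of 65) and SESA2 at -4.81 ± 0.46. The root marker PYK10 was higher (6460 against 5830 CPM, 0.16 ± 0.03) and PIN2 lower (-0.24). Leaving out single series ended the calls of PIL1 and IAA29 (without C2 Col-0 replicate 1, values -2.93 and -0.75, adjusted p = 1) and of SESA2 (without C1 Col-0 replicate 1, value -4.38, adjusted p = 1), genes of few reads, for which p in edgeR tends to 1 once a group holds 0 reads. Counts summed per series and window left 1717 genes.

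The last question was whether the responses to light and to the dawns differ between Col-0 and pifq. The light response of C1 differed between genotypes in 1 gene, AT3G52870 (2.1 ± 0.19, adjusted p = 5.54e-13), which fell in Col-0 (-1.78) and stood at 0.33 in pifq. At unadjusted p = 0.05 there were 618 genes, fewer than chance alone would give, and DESeq2 gave 29. The difference between T1 and C1 depended on genotype in 7 genes, 1 higher and 6 lower in pifq (2487 at unadjusted p = 0.05, DESeq2 125). Among them were ESM1, a gene of glucosinolate breakdown (-1 ± 0.16, adjusted p = 0.000189, -0.52 in Col-0, -1.52 in pifq), and CDI (-0.71 ± 0.13, adjusted p = 0.00663, -0.21 and -0.92). The difference between T2 and T1 depended on genotype in 2 genes, AT1G11050 (-4.33 ± 0.80, adjusted p = 0.0109) and AT4G29050 (-2.63 ± 0.46, adjusted p = 0.00848). Both had 0 reads in every library of at least 1 group compared, and so are uncertain. Without the libraries whose labels disagree only 2 of the 7 genes for T1 against C1 kept their call (5 genes in all, 4 higher and 1 lower), and CDI stood at -0.62 (adjusted p = 0.0717). Without the libraries that stood apart 26 were higher and 14 lower. No list had a member past 0.05 in these tests with edgeR. For C1 light the photoreceptor list passed camera (adjusted p = 5.19e-05) and had adjusted p = 0.796 with an estimated correlation. For T1 against C1 the morning-phased clock, dark and sugar starvation and photoreceptor lists passed camera, each with adjusted p = 0.478 with an estimated correlation. With limma-trend on real and other groupings, the count of the first interaction was matched by other groupings (2 genes, highest other 5), so chance could not be excluded for the count. The call of AT3G52870 itself was kept in every alternative, with sums per series and with each series left out. With counts summed per series and window both dawn interactions had 0 genes with edgeR, and leaving out 1 replicate series gave 1 to 32 genes for T1 against C1 and 0 to 157 for T2 against T1.

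The library labelled elf3 was a single one, C1 at ZT-0.5, and is described without a test. It stood apart in length slope (-0.28), so part of its distance from Col-0 can be technical. Its ELF3 level was 95.6 CPM, above the range of the 63 Col-0 libraries (13.1 to 64.8), so the allele was not seen as a loss of transcript. PRR9 stood at 59.5 CPM against 4.73 and 5.59 in the 2 C1 Col-0 libraries of that time (range of all Col-0 libraries 1.33 to 276), LUX at 132 (Col-0 range 2.78 to 10.3), GI at 66.7 against 11.3 and 6.9 (2.1 to 134), TOC1 at 102 (9.75 to 41.5) and PIF4 at 342 (59.8 to 185). The morning genes CCA1 (99.5 CPM, range 124 to 730) and LHY (54.2 CPM, range 75 to 880) were below every Col-0 library. ELF3 encodes a member of the evening complex, which represses PRR9, GI, LUX and PIF4.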

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

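The tests of a later start of light in C2, of a weaker response in C2, of the PIF target list at ZT0.5 and of seed material in single libraries were chosen only after the result was seen; all other tests of explanations were written before.

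Interaction tests in edgeR singled out 1 gene for the C1 light response. AT3G52870, at a mean of 55.8 CPM, changed by -1.78 in Col-0 and 0.33 in pifq (difference 2.1). For T1 against C1 the tests gave 7 genes, with the difference pifq minus Col-0 first and the values of Col-0 and pifq in brackets: CDI -0.71 (-0.21, -0.92), ESM1 -1 (-0.52, -1.52), AT4G29050 2.97 (-2.17, 0.80), AT5G16250 -0.85 (-0.24, -1.09), BTI3 -0.49 (0.11, -0.38), AT5G45670 -1.38 (-0.61, -1.98) and ORG1 -0.70 (-0.37, -1.07). For T2 against T1 they gave AT1G11050 -4.33 (3.80, -0.52) and AT4G29050 -2.63 (2.52, -0.11). AT4G29050 had a mean of 1.75 CPM. In the single elf3 library, outside all comparisons, 6 genes lay above both C1 Col-0 libraries of ZT-0.5: ELF3 at 95.6 CPM, PRR9 at 59.5, LUX at 132, GI at 66.7, TOC1 at 102 and PIF4 at 342; this difference was not tested.

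The first pattern is that PIF targets were higher in the dark in T1 and T2 than in C1. Their list mean in Col-0 was 0.93 ± 0.12 higher, and in pifq -0.04 ± 0.11, a difference of -0.96 (95% interval -1.28 to -0.64), which fits a difference that needs the PIF genes. Length bias was not seen: the difference stayed at 0.92 or more with length offsets or without the libraries that stood apart. No dark Col-0 library of T2 or C1 was among these, so that removal tested little. Handling of the ZT-0.5 libraries alone was excluded, since the difference was 1.19 at ZT0 and 0.66 at ZT-0.5. A technical difference shared by all libraries of a regime was not tested. A hypothesis is that the difference comes from PIF activity, which was not measured. PIF protein at ZT0 in C1, T1 and T2 would test it.

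The second pattern is that C2 changed little before ZT1.5. Over 3759 genes picked in T1 and T2, the C2 course came closest to that of C1 when shifted by 1 h (mean squared difference 0.117, against 0.606 with no shift; 0.122 and 0.583 in pifq), which fits light coming on 1 h later by the clock in C2. A weaker response with no delay was excluded, as the slope of the C2 change on the C1 change was 0.05 at ZT1 and 1.04 at ZT3. An exchange of dark and light C2 libraries was excluded, since 0 of the dark libraries of C2 had a light score above those of the other regimes. The labels give C2 a day 1 h shorter and do not say at which end, so most of the C2 minus C1 values may measure time since lights on.

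The third pattern is that seed storage genes were lower in pifq. Members rose and fell together between libraries of 1 group (mean correlation of residuals 0.38), but so did the dark and sugar starvation (0.493) and antenna (0.723) lists, so this test cannot tell different amounts of seed material in single libraries from genes regulated together. The list was lower in pifq in each regime (2.39 against 4.77 mean log2 CPM in C1, 2.37 against 4.24 in C2, 1.88 against 3.85 in T1 and 3.04 against 4.96 in T2). Length bias was not seen: the mean difference of -2.43 stayed at -2.42 with length offsets and was -2.62 without the libraries that stood apart. Smaller length slopes in the libraries that were kept were not tested. Whether the fall lies in seedling tissue or in seed material left on the plates could not be told and stays open.

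Whether chance can give as many genes was asked with limma-trend on 100 groupings of the same libraries, the real one among them. For the C1 light response (8588 genes, highest other 3974), T1 light (3726, 626) and T2 light (2568, 483) only the real grouping, 1 of 100, gave as many. The same held for T1 against C1 (4191, 578), T2 against C1 (2392, 450), C2 against C1 (7089, 4362) and pifq (6622, 3). Chance was therefore excluded for these counts, for libraries taken as independent. The groupings ignore what libraries of a series share (0.461 in C1 pifq replicates 1 and 2, 0.116 in T1 Col-0). Both enter genotype by T1 against C1, which had 7 genes in the main test and 0 with sums per series with edgeR (2487 at unadjusted p = 0.05), so for it chance is excluded only on that assumption. For genotype by T2 against T1 (5, highest other 6) 3 of 100 did. Chance could not be excluded for T2 against T1 (27, highest other 58; 6 of 100) and for the count of genotype by C1 light (2, highest other 5; 36 of 100), although the call of AT3G52870 was kept in every alternative.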

How the results depend on the processing

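Counts summed per series and window moved most counts: 702 genes for T1 against C1 (3202 in the main test), 722 for T2 against C1 (3392), 0 for T2 against T1 (47), 1288 for C2 against C1 (3980), 1717 for pifq (6109), and 0 for genotype by T1 against C1 (7) and by T2 against T1 (2), with edgeR. With only the groups compared in the fit there were 8920 genes for C1 light (5840), 2678 for T2 light (5769), 2253 for T2 against C1, 4 for T2 against T1, 7251 for C2 against C1, 34 for genotype by T1 against C1 and 1 by T2 against T1. Over ZT0.5 and ZT1 alone counts were 3711 for C1 light, 2500 for T1 light (5196), 2955 for T2 light, 245 for T2 against T1, and for the 3 interactions 2 (C1 light; 1 in the main test), 11 and 6. The joint test of the 4 times gave 1936 for T1 against C1, 220 for T2 against T1, 4 for genotype by C1 light and 7 by T2 against T1. DESeq2 gave 255 for T2 against T1 and 29, 125 and 103 for the interactions. limma-trend on TPM gave 4, 4 and 0 for the interactions, limma-voom 4 and 1 for the last 2, and no filter on low counts 5 for the last. With limma-trend on TPM the split of higher and lower genes moved to 1917 and 4659 for T2 light, 1178 and 1946 for T1 against C1, 1075 and 2793 for T2 against C1, 40 and 26 for T2 against T1, 2378 and 1752 for C2 against C1, and 2498 and 4054 for pifq. Of 53 list calls 34 were left with an estimated correlation.

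Without 1 replicate series at a time the counts ran from 3124 to 3666 for C1 light, 3023 to 3109 for T1 light, 3601 to 5324 for T2 light, 1298 to 3535 for T1 against C1, 1482 to 3450 for T2 against C1, 69 to 409 for T2 against T1, 2508 to 2739 for C2 against C1, 4724 to 6747 for pifq, 1 to 2 for genotype by C1 light, 1 to 32 by T1 against C1 and 0 to 157 by T2 against T1. Where this left a group with 1 library, that library is assumed to vary like the other groups.

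Alternatives chosen after seeing the data were the shift of C2 by 1 h (46 genes against 3980) and the removal of 16 libraries that stood apart, with 176 genes for T2 against T1 and 2, 40 and 35 for the interactions. With the shift the sign turned for COR27 (-0.03), BT2 (-0.13), EXPA16 (-0.03), DIN6 (-0.19), ELIP1 (0.28), PRR9 (0.12), RVE2 (-0.02), RVE4 (-0.02), RVE1 (-0.17), GI (0.06), UVR3 (-0.08), BBX31 (0.12), CHS (0.25), PAP1 (0.24), CHIL (0.04), SIG5 (0.13), ROF2 (0.32), HSFA2 (0.20), TCH2 (0.14), TCH4 (0.11) and CDF2 (-0.16). Over ZT0.5 and ZT1 alone it turned for CCA1 in C1 light (0.46), ATHB2 in T2 light (0.58), BBX32 (-0.09), UGT78D2 (-0.46) and SIG5 (-0.08) in T1 against C1, IAA29 (0.47), HY5 (-0.12), HYH (-0.19), ATHB2 (0.22), PORB (0.13) and SIG5 (-0.29) in T2 against C1, and BEE3 (0.36), ATHB2 (0.84) and PIF4 (0.23) in C2 against C1. Summed counts turned ATHB2 in T2 light (1.04) and T2 against C1 (0.03), and leaving out 1 replicate series turned PORA in T1 against C1 (-0.09 without T1 Col-0 replicate 2, up to 3.66 without C1 Col-0 replicate 2). Of all values of named genes under alternatives 11395 kept their sign and their call or lack of one, 782 lost the call and 162 gained it. Another 247 changed sign with no call in the main test or the alternative. The sign turned with a call in at least 1 of them for 38. These cover 973 named genes and comparisons.

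Replicate numbers do not pair the libraries: deviations of libraries with the same number in another regime or genotype correlated at -0.003 (2583 pairs, 18.7% over 0.1), and within a series at 0.032 (336 pairs). Some series did share deviations: 0.461 in C1 pifq replicates 1 and 2 (6 pairs each) and 0.116 in T1 Col-0 (21 pairs each), where the 2 replicates mirror each other and so give the same value. The main test treats libraries of a series as independent, and p-values that use these series may be too small; with the series as a random block 2879 genes passed for T1 against C1. With a replicate block the counts were 6181, 5467 and 6025 for C1, T1 and T2 light, 3493, 3724, 53 and 4304 for T1, T2 against C1, T2 against T1 and C2 against C1, 6257 for pifq, and 1, 7 and 2 for the interactions, all within 1.5 times of the main test. RLE size factors, length offsets and leaving out libraries with disagreeing labels moved no count that far, but without those libraries only 2 of the 7 genes of genotype by T1 against C1 kept their call, and the 5 genes past 0.05 were 4 higher and 1 lower. Depth limits the genes of few reads: at a mean under 5 CPM no gene was picked by size of change.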

Other observations

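The test of the PIF target list at ZT0.5 described here was chosen only after the result was seen, and that of the shared T2 minus T1 difference was written before. Beyond the fixed lists, gene families with at least 10 tested members were searched by symbol (158 families) with camera in each of 11 comparisons. Their p-values were adjusted within a comparison and not across the 11, so the calls below are weaker than they look. Auxin-regulated SAUR genes were lower in T2 than in C1 over the ramp in 9 of 15 cases and higher in 1 (median -1.39, adjusted p = 0.0397), and genes of the APC family were lower in 4 of 10 cases in T1 (median -0.36, adjusted p = 0.0387) and in 4 of 10 in T2 (median -0.33, adjusted p = 0.0397). On the plateau SAUR26 (-3.16) and SAUR22 (-2.90) were lower in T1 than in C1, and the GATA factor gene CGA1 (1.79 ± 0.20) and BT1 (1.85 ± 0.14) were higher.

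On the plateau 2268 genes separated C2 from C1, and 6 of 13 heat shock and excess light genes were higher (adjusted p = 0.000358 with an estimated correlation). Over the ramp 3980 genes did. On the plateau HSFA2 was 15.3 against 1.51 CPM (3.56 ± 0.44), HSP90-1 was higher (1.61), and DIN6 was lower (18.5 against 101 CPM, -2.49 ± 0.34). In C1 HSFA2 stood at 19.2 CPM over the ramp, near its C2 plateau level, so these values may reflect the 1 h delay of C2. In pifq T2 differed from T1 over the ramp in 432 genes (237 higher, 195 lower, 8 against 8 libraries). Among them were the cruciferin gene CRA1 (2340 against 607 CPM, 1.89 ± 0.44, adjusted p = 0.0106), the oleosin gene OLEO1 (1.80), CDEF1 (-1.01 ± 0.15) and the nitrate transporter gene NRT1.5 (-1.15 ± 0.21). CRA1 and OLEO1 are in the seed storage list, which was uneven between pifq libraries (mean log2 CPM 1.88 ± 1.3 in T1 and 3.04 ± 1.02 in T2, all times). P64, named above for its chloroplast-encoded reads, is among the T2 libraries. In 82.2% of these 432 genes Col-0 had the same sign, and 5 of 99 exchanges of the T1 and T2 labels of Col-0 were as high (highest 86.6%, median 50.9%), so chance alignment was not excluded.

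A first hypothesis is that the delay of red light in T2 opens a short window in which PIFs act. At ZT0.5 the PIF target list was 1.03 ± 0.19 higher in T2 than in T1 in Col-0 and 0.25 ± 0.19 in pifq, a difference of -0.77 (95% interval -1.31 to -0.24), which is consistent with a rise that needs the PIF genes. The T2 Col-0 library C63 stood apart in length slope. Without it 1 such library was left, and the values were 1.02 ± 0.24 and 0.25 ± 0.19, a difference of -0.77 (95% interval -1.38 to -0.15). In C1, where light came on in 1 step, ATHB2 and PIL1 were also higher at ZT0.5 than in T1, as given above. For these genes an early rise was thus also seen without a delay of red light. More libraries at 10-min steps between ZT0 and ZT1 in both genotypes would test the hypothesis.

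A second hypothesis is that PIF targets in the dark carry over from the previous day or evening, since their excess in T1 and T2 (difference between genotypes -0.96) was present before any light. The cause was not tested. Moving seedlings from C1 to T1 for 1 night and sampling at ZT0 would separate the last night from the history of growth.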
